A study of Mus musculus with 3 samples.

How the data were processed

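The series holds 3 two-colour arrays of mouse embryoid body RNA on an Agilent mouse expression design, each with 1 mutant and 1 wild type sample. Genotype, dye and replicate number were taken from the labels. Per the labels' protocols, total RNA was amplified and equal amounts of Cy3 and Cy5 labelled cRNA were hybridised together. The 3 arrays lie on 1 slide and have 1 scan date, so no batch could be tested.

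Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.7.3.1 and hold, for each spot, the mean intensity and the median local background intensity of both dyes, not normalized. They also hold processed intensity values, which per the file headers are background-subtracted, detrended and dye-normalized, and other columns of flags, which mark per the file headers a spot that is well above background, saturated or an outlier. Probe positions are on mm9, per the file headers. The authors' deposited value table gives log2 ratios per spot. The submitters' processing notes name limma, with version and settings not given in the sources used here. Set against the scanner values, the table's log2 ratios are mutant over wild type, with column medians of −0.04, 0.01 and −0.01 over non-control spots, and its row numbers follow the order of spots. Centring within arrays could not be told from these medians alone. The column labelled replicate 1 correlated more closely over spots with the scanner file of replicate 3 (r = 0.915) than with its own (r = 0.771), and the column labelled replicate 3 more closely with that of replicate 1 (r = 0.983) than with its own (r = 0.842). Both arrays have the same dye orientation, so the mean ratio does not depend on this.

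Analysis used R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and figures matplotlib 3.10.9. Mean signals were background-corrected with normexp (offset 50) and log ratios normalized by loess within each array, with weight 0 for 1377 control spots. On replicate 3, 7 spots carried a background outlier flag and a local background above 10 times the array's median, up to 190723 intensity units in Cy3. With them the fitted mean of the background residual on that array was −1528 in Cy3 and −954 in Cy5, against −11.0 and −16.6 when they took the array's median background, so the second fit was used and the 7 spots were left out. The need for this was seen in the fitted background parameters, and the rule was set after signals and these fits had been examined but before any gene was tested. The fit with all spots was run later, and the choice decides whether any gene is called. Outlier-flagged spots were left out, 317, 364 and 440 on the 3 arrays. The sign of each array was turned to mutant over wild type, and spots of a probe were averaged.

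Of 39429 probes, 26761 (67.9%) had an accession in the reference table of assembly GRCm38.p6, which was used for symbols only, and 2878 of these received another symbol than the file's. The file's name was kept for the rest. Probes well above background on all 3 arrays in at least 1 genotype were kept (19140), and for a gene with several the probe with the highest mean signal was used, which left 15426 genes. Of the called genes 11 had a further tested probe, and 10 of these 11 probes had the same sign, while those of Paip1 (0.27 against −3.50) and Gpa33 (0.02 against 2.73, a gene chosen after its values were seen) differed less than 2-fold between genotypes. Log ratios were tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit has 2 residual degrees of freedom and 3.04 prior ones. Where a probe was not well above background on any array of a genotype, the fold is a lower bound from the 2 channels after loess and Aquantile scaling. It sets the mean of the brighter genotype against the mean, per array, of the higher of the lowest signal among probes well above background and the probe's own. The dyes were not swapped equally, so such bounds are open to dye bias, as are the mean ratios.

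Each array is a pair of 1 mutant and 1 wild type sample, so the ratio fit is paired by array. Deviations of the 2 channels from their genotype means correlated over genes at 0.515, 0.016 and 0.462 on replicates 1, 2 and 3. Over genes, which are not independent replicates, ratios correlated at 0.879 between replicates 1 and 3, at 0.151 between 1 and 2 and at 0.180 between 2 and 3.

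There were 40 gene lists, fixed before the data were examined, and 38 with at least 3 measured genes were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. None of the 13 called lists was called with an estimated correlation, and fry called 1, the cardiac list. With the estimated correlation 0 lists had an unadjusted p under 0.05. That form of camera rests on the 2 residual degrees of freedom, so it had little power whatever the correlation. The cardiac list, with an estimated correlation of −0.042, went from an unadjusted camera p of 0.000899 to 0.0685. Most called lists had an estimated correlation above the preset, up to 0.761 for the neural list. For these the camera p at the preset may be too small. A member of the list of genes near Dido1, Bhlhb9, lies on the X chromosome and entered through an older symbol. The genes named are Dido1, the 10 largest changes each way among called genes with the same sign on all arrays (without RIKEN, clone and predicted gene names), up to 4 members of smallest p from each called list, 12 fixed markers, and Xist and the Y-linked genes. The value of 1 gene that this rule takes is not reported here. This rule and the alternatives were fixed before the data were examined, apart from the fit with all spots in the background model and the removal of base composition, which were added afterwards.

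The fit was tested on simulated data for this comparison, with 15426 genes, the prior variance of the real fit and 200 changed genes. It recovered 0% of changes of 1 on the log2 scale, 12% of 2, 86% of 4 and 98% of 6, with 3 false calls. The simulated noise was independent between arrays and held no dye effect. The real ratios correlated weakly across the dye swap, so recovery and false calls in these data may differ. Alternatives covered the background correction, offset, normalization within and between arrays, dim probe filter, dye term, pairing, probe choice, variance moderation, thresholds, the authors' values and each replicate left out.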

Results

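RNA from mouse embryoid bodies was compared between wild type cells and cells with a C-terminally truncated Dido3 protein (Dido3ΔCT). Embryoid bodies are aggregates of embryonic stem cells that differentiate in suspension, and these had been grown for 10 days without the self-renewal factor LIF. Dido3 is the longest protein of the Dido1 locus. The series title places the locus between self-renewal and differentiation of embryonic stem cells, and the comparison asks which transcripts differ between the genotypes. There were 3 mutant and 3 wild type samples, described in the labels as biological replicates, hybridised as 3 mutant and wild type pairs on 3 two-colour arrays of 1 slide. Whether the replicates come from separate cell lines or from repeat cultures of 1 line per genotype was not established here. In the second case the p-values measure spread between cultures and arrays, and genotype cannot be told apart from other differences between the lines. Mutant RNA carried Cy3 on replicates 1 and 3 and Cy5 on replicate 2. Between 46.5% and 62.5% of the non-control spots were well above background in the mutant channel and between 48.5% and 74.4% in the wild type channel. Values below are mean log2 ratios of mutant over wild type with the SE of the limma fit over 3 arrays, and the small number of arrays limits their precision. The dyes were not swapped equally, so each mean keeps part of any dye effect of its gene. With a dye term Zic1 moved from −5.41 to −4.61 and Lefty2 from 1.63 to 1.88.

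Dido1, the targeted gene, was read by 4 probes that did not move together. They lie on chromosome 2 of mm9, minus strand. The probe used for the gene, from 180393086 to 180393145 near the 3′ end, is annotated to transcript variant 3 and gave a log2 ratio of 1.74 ± 0.27 (adjusted p = 0.0580, limma), a 3.33-fold higher mean that was above 0 on all 3 arrays and did not pass the threshold. The probe from 180419747 to 180419806, shared by 3 annotated transcripts, was well above background on 2 of the 3 arrays in the wild type. It gave 1.12 ± 0.45 (SD, n = 3), with a limma adjusted p of 0.118 over all probes. The probe from 180405604 to 180405663, annotated to variant 2, was not well above background in the wild type on any array and was at least 2.17-fold higher in the mutant samples, with an adjusted p of 0.123 over all probes. The probe from 180415861 to 180415920, annotated to variant 1 alone, gave −1.92 ± 0.49 (SD, n = 3), with an adjusted p of 0.0593 over all probes. The ratio of the variant 1 probe minus that of the 3′ probe averaged −3.66 ± 0.48 and was below 0 on each array (SD, n = 3). The labels do not give the limits of the deletion, so these probes do not check the genotype labels. The 3′ probe passed with a dye term (adjusted p = 0.00339), without replicate 2 (1.52, adjusted p = 0.00295) and with base composition removed (adjusted p = 0.0324), and adjusted p ran from 0.00295 to 0.385 over 20 alternatives. The fits with a dye term and without replicate 2 take their residual error from replicates 1 and 3 alone, which share a dye orientation. Without replicate 2 genotype and dye cannot be told apart. With the mean over the gene's probes the ratio was 0.57.

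**Figure D1:**
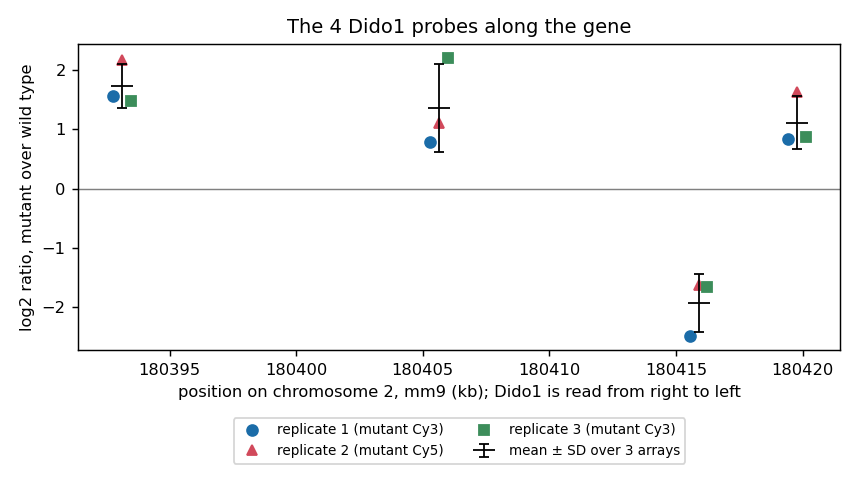
Log2 ratio of mutant over wild type (vertical axis) at the 4 Dido1 probes, placed by their position in kb on chromosome 2 of mm9 (horizontal axis); symbols are the 3 arrays, and bars are the mean ± SD. The probe from 180415861 averages −1.92, and those from 180419747 and 180393086 average 1.12 and 1.74, while at the probe from 180405604 the wild type was not well above background and the ratios are no exact size.

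In mutant embryoid bodies 32 genes were higher and 14 lower among 15426 tested, and all 46 moved the same way on the 3 arrays. A call with 3 arrays nearly requires this, so it is no separate support. Of all tested genes 44.3% had the same sign on the 3 arrays, against 25% by chance. Replicates 1 and 3 shared the sign for 84.3% of genes, but replicate 2 shared it with them for only 51.3% and 53.1%. Of the X-linked lymphocyte-regulated family, encoded in a cluster on the X chromosome, 6 genes rose: Xlr5c by 5.58 ± 0.23, Xlr5b by 5.53 ± 0.26, Xlr5a by 4.51 ± 0.33, Xlr3a by 4.17 ± 0.35, Xlr4a by 4.06 ± 0.38 and Xlr4b by 3.91 ± 0.30 (adjusted p from 0.0196 to 0.0432). These genes are near copies of each other and several of the probes are annotated to more than 1 of them, so the single members are uncertain and not independent. Xlr5a was well above background on 2 of the 3 wild type arrays. Cyct, the testis form of cytochrome c, rose 29.2-fold (4.87 ± 0.24), Nr0b1, a nuclear receptor of embryonic stem cells, 15.1-fold (3.92 ± 0.34), Mep1b, a meprin metalloprotease subunit, 10.8-fold (3.44 ± 0.30), and the alpha-tubulin gene Tuba3a 10.3-fold (3.36 ± 0.32). Tuba3a also belongs to a family of near copies.

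Among the genes that fell, Dlk1, an imprinted transmembrane protein related to Notch ligands, had a log2 ratio of −4.22 ± 0.35, Myl3, a myosin light chain of heart and slow muscle, −3.95 ± 0.35, and Hbb-bh1, an embryonic globin, −3.91 ± 0.34. Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, gave −3.12 ± 0.28, Smarca2, a chromatin remodelling ATPase, −3.10 ± 0.25, Eef1akmt2, a methyltransferase of an elongation factor, −3.16 ± 0.26, and Rbp4, the retinol carrier, −2.69 ± 0.25, with adjusted p between 0.0417 and 0.0432. Paip1, which binds the poly(A)-binding protein, gave −3.50 ± 0.27 at its brightest probe, which was well above background on 2 of the 3 mutant arrays, while its other tested probe gave 0.27 ± 0.75 (SD, n = 3). The Y-linked genes Eif2s3y and Ddx3y also fell (adjusted p = 0.0372 for both). Eif2s3y had a log2 ratio of −6.17 ± 0.36 and was well above background on 1 of the 3 mutant arrays, and Ddx3y was not well above background on any mutant array, at least 21.2-fold lower. Rbmy, a Y-linked gene of male germ cells, had −2.25 ± 0.36 (adjusted p = 0.0603), with 1 of the 3 mutant arrays above background, while its other probe had −0.49 ± 0.39 (SD, n = 3). The 2 probes of Ube1y1 disagreed. The brighter was above background on all arrays and had 0.26 ± 0.31 (adjusted p = 0.649), from −0.0082 to 0.56 with 1 replicate left out and −1.44 with the mean over both probes, and the other was not well above background on any mutant array (adjusted p = 0.0626 over all probes). Rbmy passed without replicate 2 (−2.47, adjusted p = 0.00449), with a dye term (adjusted p = 0.0081), with base composition removed (adjusted p = 0.0356) and with unpaired channels (adjusted p = 0.0481), and its adjusted p ran from 0.00449 to 0.414 over alternatives. As for Dido1, the fits without replicate 2 and with a dye term rest their residual error on replicates 1 and 3 alone, and the former cannot separate genotype from dye. Neither of the 2 Xist probes was well above background in either genotype, and other named Y-linked genes did not pass the filter on dim probes.

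Adjusted p-values crowded just above the threshold, with 651 genes higher and 587 lower below 0.1. On replicate 3, 7 spots with extreme local background were kept out of the background model, a choice made after signals and fitted backgrounds had been seen but before any gene was tested, and it decides whether any gene is called. With those spots in the model limma called 0 genes either way, with 1684 at an unadjusted p under 0.05, and in the authors' deposited values it also called 0, with 3057 at an unadjusted p under 0.05. The counts became 2449 and 2300 with a dye term, 3963 and 3345 without replicate 2, 3 and 2 without replicate 1, and 9 and 9 without replicate 3, of which 8 and 7 were among the 32 and 14. They were 179 and 96 with the channels taken as unpaired samples (no replicate block), 4 and 3 with median centring and 63 and 46 with scaling between arrays. Genes higher in the mutant made up 69.6% of the called genes, against 57.1% with median centring and 57.8% with scaling.

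**Figure D2:**
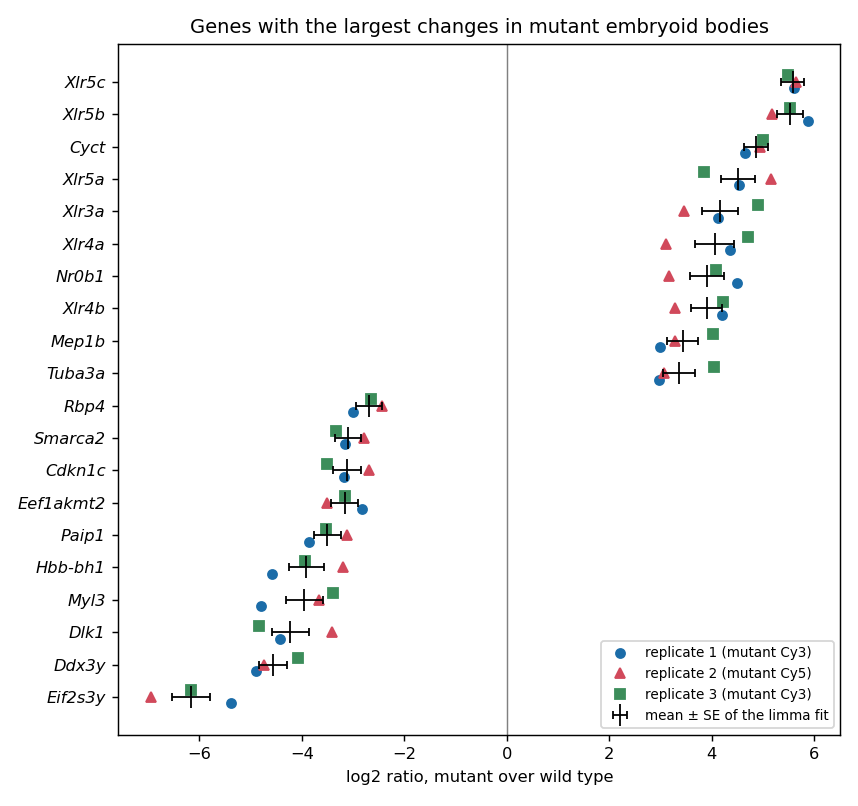
Log2 ratios of mutant over wild type (horizontal axis) for the 10 named genes with the largest rise and the 10 with the largest fall among those called; symbols are the 3 arrays, and bars are the mean ± SE of the limma fit. Ratios run from −6.17 for Eif2s3y to 5.58 for Xlr5c. The arrays of each gene lie on the same side of 0, which the rule for choosing these genes required. The mutant signal of Ddx3y was not well above background and its ratios are no exact size.

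Pluripotency genes as a list lay higher in the mutant than other genes, with a median log2 ratio of 2.10 over 28 members and array medians of 2.01, 1.61 and 2.26 (camera, adjusted p = 1.42e-11; adjusted p = 0.598 with an estimated correlation). Of the 28, 4 rose, 0 fell and 24 did not pass the test over all genes. Adjusted over the list alone, 19 were higher and 2 lower. Those that rose were Zfp42 (also called Rex1, a naive-state marker) by 3.17 ± 0.26, Nr0b1, Dppa5a by 2.67 ± 0.24 and Dppa2 by 2.79 ± 0.25, whose other probe had 1.87 ± 1.67 (SD, n = 3). Pou5f1, the gene of the core factor Oct4, had a ratio of 1.99 ± 0.28 (adjusted p = 0.0559) and Sox2 1.05 ± 0.25 (adjusted p = 0.101). Nanog had 0.08 ± 0.26 (adjusted p = 0.883), and from −0.018 to 0.27 with 1 replicate left out. The 2 lower members were Klf4, at −1.14 ± 0.31 (adjusted p = 0.122), and Lin28b, at −1.38 ± 0.33, which was chosen after its value was seen.

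Of the 13 primed epiblast genes 1 rose, 0 fell and 12 did not pass (list adjusted p = 0.00875; adjusted p = 0.598 with an estimated correlation), and 5 were higher and 0 lower when adjusted over the list alone. The amino acid transporter gene Slc7a3 rose by 2.61 ± 0.24, and the transcription factor genes Pou3f1 and Foxd3 had ratios of 2.25 ± 0.24 and 3.01 ± 0.36, with Foxd3 above background on 2 of the 3 wild type arrays. The DNA methyltransferase gene Dnmt3b had 2.07 ± 0.30. The primitive streak list was also higher (median 0.45 over 11 genes, adjusted p = 0.0319; adjusted p = 0.621 with an estimated correlation), with 0 members past the test over all genes and 2 higher, 0 lower adjusted over the list alone. The signalling genes Nodal, at 1.93 ± 0.25, and Lefty2, at 1.63 ± 0.39, had the largest ratios among its 4 members of smallest p, Eomes had 0.73 ± 0.30, and 0.44 without replicate 2, and Cer1 0.51 ± 0.27. T, the Brachyury gene, had −0.047 ± 0.24 (adjusted p = 0.927), and from −0.12 to 0.023 with 1 replicate left out. Without replicate 2 neither the epiblast list (adjusted p = 0.278, range over its alternatives 0.000215 to 0.598) nor the primitive streak list (adjusted p = 0.217, range 0.00461 to 0.621) was called. The latter was also lost in the authors' values (adjusted p = 0.0508) and with base composition removed (adjusted p = 0.0735). The primitive streak median was 0.22 without replicate 2 and 0.73 without replicate 1, with 0.14 as the lowest over its alternatives, and the epiblast median ran from 0.15 to 0.57.

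Germ cell and meiosis genes were higher as a list, with a median of 1.56 over 17 members (adjusted p = 1.17e-05; adjusted p = 0.598 with an estimated correlation). Of these 1 rose, 0 fell and 16 did not pass, and 11 were higher and 1 lower when adjusted over the list alone. Syce1, a component of the synaptonemal complex, rose by 2.76 ± 0.23, the meiotic cohesin gene Stag3 had 2.08 ± 0.30 and Hormad1, of the meiotic chromosome axis, 2.85 ± 0.54. The receptor gene Kit had −1.92 ± 0.35. The 9 interferon response genes had a median of 0.71 (adjusted p = 0.0190; adjusted p = 0.621 with an estimated correlation), with 0 past the test over all genes and 4 higher, 0 lower adjusted over the list alone. Oasl2 had a ratio of 3.55 ± 0.37 (adjusted p = 0.0502), Ifitm3 1.81 ± 0.29, Ddx58, the gene of the RNA sensor RIG-I, 1.09 ± 0.24, and Oas1a, above background on 2 of the 3 wild type arrays, 1.10 ± 0.34. The interferon list was not called without replicate 2 (adjusted p = 0.135) or without a filter on dim probes (adjusted p = 0.105), with a range of 0.000463 to 0.621 over its alternatives. Its median was 0.46 without replicate 3 and ran from 0.21 to 1.09 over the alternatives, and that of the germ cell list from 0.89 to 2.15.

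Both lists of extraembryonic endoderm were called lower by camera and neither with an estimated correlation. The parietal endoderm and basement membrane list had a median of −2.79 over 16 members and array medians of −3.72, −1.93 and −2.60 (adjusted p = 1.42e-11; adjusted p = 0.598 with an estimated correlation). All 16 were below 0 on every array, none passed the test over all genes, and 15 were lower and 0 higher adjusted over the list alone. The laminin genes Lama1 and Lamb1 had ratios of −3.69 ± 0.47 and −2.82 ± 0.38, the receptor gene Pdgfra −2.87 ± 0.35 and the transcription factor gene Sox7 −2.51 ± 0.27. In the visceral endoderm list, which holds the secreted lipid and transport proteins of the yolk sac, the median was −1.52 over 22 members (adjusted p = 7.49e-09; adjusted p = 0.598 with an estimated correlation). Of these 1 fell, Rbp4, 0 rose and 21 did not pass, and 11 were lower and 0 higher adjusted over the list alone. Afp, the gene of alpha-fetoprotein, had −2.23 ± 0.24 (adjusted p = 0.0502), the apolipoprotein gene Apoa2 −2.35 ± 0.28 and the endocytic receptor gene Cubn −1.81 ± 0.24.

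The definitive endoderm list was lower with a smaller median, −0.44 over 14 members (adjusted p = 0.0342; adjusted p = 0.621 with an estimated correlation). None of its members passed over all genes, and 4 were lower and 0 higher adjusted over the list alone. These 4 are transcription factors that extraembryonic endoderm also uses: Gata6 at −2.80 ± 0.40, Sox17 at −2.60 ± 0.45, Foxa2 at −1.72 ± 0.31 and Gata4 at −1.89 ± 0.52. This list was not called with a dye term (adjusted p = 0.0722), with median centring (adjusted p = 0.141), in the authors' values (adjusted p = 0.0559) or without replicate 2 (adjusted p = 0.0821), with a range of 0.00321 to 0.621. The median was −0.25 without replicate 1 and −0.82 with both channels above background, the ends of its range.

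The neural list had a median of −0.95 over 18 members (adjusted p = 0.000361; adjusted p = 0.683 with an estimated correlation), but the arrays differed, with medians of −1.20, −0.05 and −1.96. None of its members passed over all genes, and 8 were lower and 0 higher adjusted over the list alone. Zic1, a transcription factor gene of the neural plate, had ratios of −6.78, −2.21 and −7.26 on the 3 arrays (adjusted p = 0.0729) and was above background on 2 of the 3 mutant arrays, with a second probe at −0.63 ± 0.98 (SD, n = 3) that was too dim to test. Sox1 had −5.02, −2.03 and −5.09 (adjusted p = 0.0625), with a second probe at −0.26 ± 0.17 (SD, n = 3) that was also too dim to test. The neural list was not called among genes well above background in both channels (adjusted p = 0.118, range 3.84e-06 to 0.683). Its median was −1.59 without replicate 2 and −0.50 without replicate 3. Fabp7, a marker of radial glia, had −3.83 ± 0.76 and Pax3 −2.03 ± 0.38, both above background on 2 of the 3 mutant arrays. Pax6 was too dim to be tested.

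Cardiac genes were lower as a list, with a median of −0.42 over 20 members (adjusted p = 0.00488; adjusted p = 0.598 with an estimated correlation; fry adjusted p = 0.0222). Of these 1 fell, Myl3, 0 rose and 19 did not pass, and 6 were lower and 1 higher adjusted over the list alone. The sarcomere genes Myh7, Myl7 and Tnnc1 had ratios of −2.25 ± 0.31, −1.69 ± 0.25 and −2.15 ± 0.32, with Myh7 and Tnnc1 above background on 1 of the 3 mutant arrays. Myh6, the alpha heavy chain of cardiac myosin, had 1.81 ± 0.34 (adjusted p = 0.0716). Among 11 blood genes 1 fell, Hbb-bh1, 0 rose and 10 did not pass, and 6 were lower and 1 higher adjusted over the list alone (median −0.78; list adjusted p = 0.0425; adjusted p = 0.621 with an estimated correlation). The globin genes Hba-x and Hba-a1 had −2.74 ± 0.51 and −1.88 ± 0.44, above background on 1 and 2 of the 3 mutant arrays, and Ahsp, whose product stabilises free alpha globin, was not well above background on any mutant array, at least 1.36-fold lower (adjusted p = 0.150). The higher member was Gata1, at 0.72 ± 0.24, chosen after its value was seen. The blood list was not called with Agilent's processed signals (adjusted p = 0.0659), with median centring (adjusted p = 0.153), with both channels above background (adjusted p = 0.271), in the authors' values (adjusted p = 0.0789) or with all spots in the background model (adjusted p = 0.0987), with a range of 0.0101 to 0.621, and its median ran from −1.21 to −0.22.

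Mesenchyme and extracellular matrix genes, which are also those of feeder fibroblasts, had a median of −0.46 over 18 members and array medians of −0.50, 0.06 and −0.91, so that replicate 2 did not lie lower (adjusted p = 0.0342; adjusted p = 0.683 with an estimated correlation). None passed over all genes, and 5 were lower and 2 higher adjusted over the list alone. Igfbp5 had −3.95 ± 0.44, Timp3 −2.30 ± 0.24 and Postn −2.10 ± 0.28, while the 2 higher members were the surface protein gene Thy1, at 2.00 ± 0.31, and Cthrc1, at 0.93 ± 0.27, above background on 2 of the 3 wild type arrays and chosen after its value was seen. This list was not called in 8 of 22 alternatives, among them a dye term (adjusted p = 0.0866), median centring (adjusted p = 0.130) and without replicate 3 (median −0.25, adjusted p = 0.0677), with a range of 0.0149 to 0.683. The 5 measured Hox genes of paralogue groups 1 to 4 had a median of −1.02 (adjusted p = 0.00219; adjusted p = 0.598 with an estimated correlation), with 0 past the test over all genes and 4 lower, 0 higher adjusted over the list alone. Hoxb4 had −1.45 ± 0.25, Hoxb2 −1.02 ± 0.25 and Hoxa3 −1.10 ± 0.33, or −0.72 without replicate 3, with Hoxb2 above background on 1 and Hoxa3 on 2 of the 3 mutant arrays. The median of this list ran from −1.87 to −0.50 over its alternatives.

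With an estimated correlation 0 of the 38 tested lists were called by camera, and 0 had an unadjusted p under 0.05. That test rests on 2 residual degrees of freedom and had little power, so it does not decide on any list. The estimated correlation was 0.761 for the neural, 0.551 for the parietal endoderm and 0.171 for the pluripotency list. Among called lists only the cardiac (−0.042) and epiblast (−0.080) lists lay below the preset 0.01. Where members correlate above the preset, the camera p at the preset is too small, so the small values above may overstate the evidence. Fry called 1, the cardiac list, and gave the other called lists adjusted p from 0.0663 to 0.351. The pluripotency, germ cell, visceral endoderm, parietal endoderm and anterior Hox lists were called in the other 20 of 22 alternatives. All 20 kept the preset correlation of 0.01, so they do not test that assumption, and the 2 alternatives that dropped it called none of these lists. Not all of the 20 could differ. Trend and robust moderation and the 2-fold minimum leave the list test unchanged, and a threshold of 0.1 can only keep a call.

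**Figure D3:**
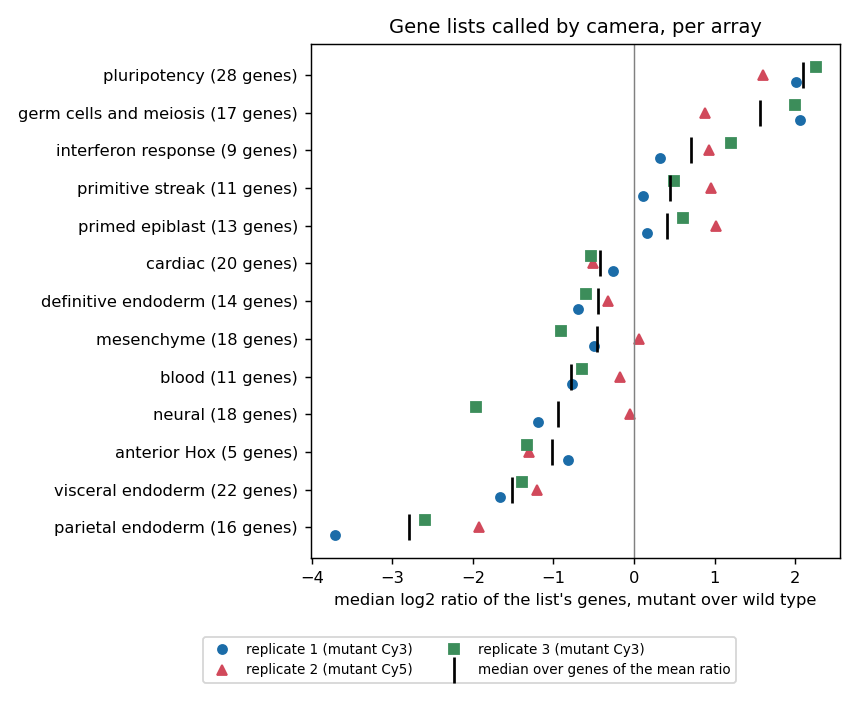
Median log2 ratio of mutant over wild type (horizontal axis) of the genes in each of the 13 lists called by camera; symbols are the medians on the 3 arrays and black bars the median over genes of the mean ratio. Medians run from −2.79 for parietal endoderm to 2.10 for pluripotency, and replicate 2 lies nearest 0 for the neural list.

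The other 25 tested lists were not called. Adjusted over the list alone, some of these also had members past the threshold. The Nodal and BMP list had 3 higher and 4 lower of 18, the heat shock and endoplasmic reticulum stress list 3 and 4 of 17, and the mitosis list 0 of 25. Over all genes 3502 of 15426 had an unadjusted limma p under 0.05, so counts over a list alone do not by themselves set a list apart. Imprinted genes (adjusted p = 0.0505), neural crest (adjusted p = 0.0588) and the primary cilium (adjusted p = 0.0762) came closest, and mesoderm transcription factors (median −0.02 over 16 genes, adjusted p = 0.862) and endothelium (median −0.42 over 13 genes, adjusted p = 0.680) did not separate from other genes. Kdr, the VEGF receptor gene of that list, had −0.61 ± 0.24 (adjusted p = 0.223), with a second probe at −0.18 ± 1.18 (SD, n = 3), and Cdx2, a caudal-type homeobox gene, −1.71 ± 0.29 (adjusted p = 0.0631), above background on 2 of the 3 mutant arrays. The posterior Hox list had a median of 0.57 and a mean of 0.04 but a test in the lower direction, hypoxia and glycolysis genes had a median of 0.20 and a mean of −0.02, and the Nodal and BMP list and the neighbours of Dido1 had negative medians, −0.10 and −0.08, with means of 0.01.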

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

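The fit with all spots in the background model and the removal of base composition were chosen after the data had been examined. Keeping 7 spots out of that model was set before any gene was tested, and it decides whether any gene is called. The smallest fold among called genes was 5.69, so a 2-fold minimum could remove none. With that minimum and with trend and robust moderation, the counts of 32 higher and 14 lower genes held within 1.5 times. They were 97 and 64 without background correction, 282 and 185 with Agilent's processed signals, 116 and 70 with offset 16, 4 and 3 with median centring, 63 and 46 with scaling between arrays, 1 and 1 without a filter on dim probes, 3 and 1 with both channels above background, 2449 and 2300 with a dye term, 75 and 43 over all probes, 67 and 36 with the mean over a gene's probes, 651 and 587 at a threshold of 0.1, 0 and 0 in the authors' values, 0 and 0 with all spots in the background model (limma, 3057 and 1684 genes at an unadjusted p under 0.05), and 735 and 598 with base composition removed. In these, the larger counts held all 46 genes, except for the mean over probes, which held 30 and 13 of them. Leaving out a replicate gave 3 to 3963 higher and 2 to 3345 lower genes, with the high values without replicate 2, the only array with the dyes swapped. Without the array pairing, as separate channels with no replicate block, 179 and 96 genes were called, including 30 and 11 of the 32 and 14, and the numbers of called lists were 5 and 10. The dye term leaves 1 residual degree of freedom, and tests with fewer arrays or more genes change the adjustment by construction. Fits with a dye term and without replicate 2 take their residual error from replicates 1 and 3 alone, which share a dye orientation. Without replicate 2 genotype and dye cannot be told apart. For other settings the cause was not tested.

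Median centring moved the median of all genes to −0.22 from 0.03. The share of higher among called genes was 69.6% with loess, 57.1% with median centring and 57.8% with scaling between arrays. The Dido1 ratio stayed positive in each alternative and passed with a dye term (1.84), at a threshold of 0.1 (1.74) and with base composition removed (1.73), with adjusted p from 0.00295 to 0.385 over alternatives. Leaving out a replicate gave 1.52 to 1.87, and it passed without replicate 2 only. The called lists, 5 higher and 8 lower, became 0 and 0 with an estimated correlation and 0 and 1 with fry. In the authors' values 4 and 5 were called. Leaving out a replicate gave 3 to 6 higher and 7 to 9 lower lists, with 3 higher without replicate 2. The Nanog ratio of 0.08 changed sign with a dye term (−0.017), in the authors' values (−0.0067), with all spots in the background model (−0.0082) and without replicate 1 or 3 (leave-one-out range −0.018 to 0.27), and T without replicate 2 (range −0.12 to 0.023). Ube1y1 changed sign with the mean over its probes (−1.44), which disagree, and without replicate 2 (range −0.0082 to 0.56). No other named gene or called list changed direction in these alternatives, with 151 gene results losing and 252 gaining a call and 47 list results losing one. Signal over background limits the rest: genes not well above background on all arrays of at least 1 genotype, Pax6 and Xist among them, were not tested.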

Other observations

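The tests of base composition were set after the uncorrected values but before the corrected ones were seen. The tests on sex-linked genes, on the dilution of differentiated cells and over sign patterns were chosen after their results were seen, the test on the Y chromosome was widened after further Y-linked probes had been examined, and the comparison with the spread of list members was added after the list medians were known. The imprinted genes named here beyond Dlk1 and Cdkn1c, and Tcfl5, were picked after their values were seen.

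Of 20 imprinted genes measured, 2 fell, Dlk1 and Cdkn1c, 0 rose and 18 did not pass, and 6 were lower and 2 higher when adjusted over the list alone (list adjusted p = 0.0505). Ratios differed between genes of the same imprinted region. Igf2, the growth factor gene, had −3.25 ± 0.72 and its neighbour H19, a non-coding RNA, 2.29 ± 0.97, while Dlk1 had −4.22 ± 0.74 and its neighbour Meg3 −0.14 ± 0.02 (SD, n = 3). Snrpn had 2.06 ± 0.34 and Gnas −2.04 ± 0.57.

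Beside Dido1 on chromosome 2, Tcfl5, a transcription factor gene of male germ cells, rose by 3.15 ± 0.27 (SE, adjusted p = 0.0417), and the other neighbours did not pass, with Arfgap1 at −1.68 ± 0.28. Of the 32 genes that rose, 11 lie on the X chromosome, 6 of them of the Xlr family, whose probes are not independent, against 657 X-linked genes among the 15426 tested.

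Ratios of replicate 2 correlated weakly with the mean of replicates 1 and 3 (r = 0.171 over genes), and base counts of the probe explained 35.4% of the variance of their difference. A dye bias set by base composition may account for part of this, since removing it raised r to 0.373, still below the 0.867 between replicates 1 and 3 treated alike. A different state of the cultures behind replicate 2 also stays open. Pairs of probes of the same gene (2640) correlated in this difference at 0.253 after the removal, against 0.713 for the ratios themselves. The neural list kept a median difference of 1.73, but its array medians had already set replicate 2 apart, so this restates that observation. Replicate 2 is the only array with its dye orientation, so dye and culture cannot be told apart for what remains.

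Eif2s3y and Ddx3y were well above background in 1 of 6 mutant channels and in 6 of 6 wild type channels. Of 23 other probes placed on the Y chromosome, 8 were well above background on all 3 mutant arrays and 10 on all 3 wild type arrays, among them the brighter Ube1y1 probe in both. A line without a Y chromosome in most mutant cells and silencing of some Y-linked genes are candidate explanations that cannot be told apart here, since such probes may read copies elsewhere in the genome, which was not tested. A second active X chromosome in the mutant cells is argued against by X-linked genes, whose median lay 0.066 ± 0.113 (SD, n = 3) above that of 14583 autosomal genes. The median does not bear on a second X chromosome that is inactive, so it does not settle the sex of the cells. Xist was not well above background in either genotype, but its 2 probes were dim throughout and exclude nothing.

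Camera at the preset correlation called the pluripotency list higher and lists of several differentiated types lower, but with an estimated correlation it called 0 of 38 lists (smallest adjusted p = 0.598), and 4 of the 28 pluripotency genes passed over all genes. With 2 residual degrees of freedom the test with an estimated correlation had little power. The estimated correlation of the pluripotency list, 0.171, also lay above the preset 0.01, so its camera p at the preset may be too small. A dye bias set by base composition is argued against as the whole cause, since the median of the pluripotency list with base composition removed was 2.02 ± 0.22 (SD over arrays, n = 3). Lists of differentiated types did not move alike. The median of the parietal endoderm list, the lowest, minus that of the mesoderm list was −2.85 ± 1.03 (SD, n = 3). A larger share of undifferentiated cells would lower all lists alike only for genes silent in those cells and read without compression. Neither condition was tested, so such a dilution stays open as a cause. The mesoderm median of −0.02 lay above the −2.79 of parietal endoderm by more than the SD of its 16 members (1.05), and so it did over the 11 well above background in both channels (0.10, SD 1.05). That filter drops members whose mutant signal fell to background, so the 11 do not weigh against dilution. Unequal changes in the shares of cell types, the difference in genotype and any other difference between the cell lines or cultures stay open and were not tested.

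Sign patterns of the 3 arrays number 4, too few for a share under 0.05, and 1 of the 4, the real one, gave as many higher genes (32, highest other 0), as many lower genes (14, highest other 0) and as many called lists (13, highest other 9). The pattern that turns replicate 2, which follows the dyes, called 0 genes with limma but had 2498 genes at an unadjusted p under 0.05, against 3502 for the real pattern and 15 and 12 for the others.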
